A study of Bdellovibrio bacteriovorus with 12 samples.

How the data were processed

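RNA was sequenced from the predatory bacterium Bdellovibrio bacteriovorus strain 109J, which swims freely in its attack phase and then grows inside the periplasm of a prey bacterium (intraperiplasmic growth). Cells in either phase were exposed for 30 min to 50 µM of diffusible signalling factor (DSF), a fatty acid signal released by other bacteria, or were left unexposed. Per the labels, the cells came from independent overnight cultures of 150 ml, which were passed through a 0.45 µm filter and concentrated 10-fold, and in attack phase parts of them were kept at 30 °C with DSF or without it. For intraperiplasmic growth the predator was mixed with Escherichia coli MG1655 prey at an optical density of 4.3 ± 0.2, kept in buffer for 1 h beforehand, and DSF or sterile buffer was added 2 h into the infection. The 12 libraries make 4 groups of 3. The labels give replicate numbers, but they do not say which libraries share a culture, a day or a sequencing batch.

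The deposited table holds 1 row per coding gene, with a locus tag, a product name and, for 3600 genes, coordinates. The authors deposited expected counts per gene from Salmon (version not given), not normalised between libraries. The authors also deposited TPM (counts scaled for gene length and library size) for the same libraries. The other deposited columns are the authors' linear ratios of mean TPM, DSF over untreated, and p-values after a correction whose method is not named. The genome build, the annotation, the library kit and its strandedness are not given in the sources used here. Of 3618 rows, 1 had a blank count cell and was left out, which left 3617 genes. Of the count values, 1.61% were not whole, in 137 genes, and they were rounded. The table has no ribosomal RNA rows and no prey rows, so the share of reads that came from prey was not analysed here. The planned removal of ribosomal and transfer RNA rows was therefore not run, and a list of predation genes fixed by the locus tags of another strain was not used here.

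Library totals ranged from 13746980 to 20057556 counts. Averaged over genes, the spread between libraries of a group was 10.4 to 62.3 times the counting variance. This average leans on abundant genes, for which the precision is set by the 3 libraries per group. Of the 3515 tested genes, 869 had a mean count of at least 200 in both phases, so counting error is not small for every gene. The common biological coefficient of variation was 0.104.

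Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which removed 102 and left 3515 tested genes. Libraries were scaled with TMM factors, and 1 quasi-likelihood model with robust dispersions and 1 coefficient per group was fitted to all 12 libraries. The 4 comparisons were DSF against untreated in attack phase, the same in intraperiplasmic growth, the difference of these DSF effects (the interaction) and the untreated phases against each other. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All tests were two-sided. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change over the square root of F. This is an approximation. It is too small for large folds from a group with few reads, such as those of EP01_RS08250. Levels are TMM-normalised CPM (counts scaled for library size) as mean ± SD over the 3 libraries of a group. They are relative to the scaling factors, so they are not shares of a library.

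Gene lists were fixed by patterns on product names before the data were examined. They number 34, of which 31 had at least 5 measured members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 31 lists of a comparison. Camera with an estimated correlation and fry were run as alternatives. Because patterns were matched without regard to capitals, 53 list entries in 5 lists matched an acronym inside a longer word. Of these, 23 are among the 66 members of the efflux list, such as glutamate and chorismate enzymes, 17 among the 116 regulators, 9 among the 30 DNA repair genes, 3 in the peptidoglycan list and 1 in the lipopolysaccharide list. The lists were kept as fixed, and lists without these entries were added as an alternative.

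Genes named in the text follow a rule also fixed before the data were examined. In each DSF comparison they are called genes with a mean of at least 20 CPM over the 6 libraries and with all 3 DSF libraries on one side of all 3 untreated ones. Named were the 6 annotated genes with the largest rise and the 6 with the largest fall, the 2 largest in each direction among genes without an annotated function, and the 2 members with the smallest p of each called list. The interaction and the phase comparison name 5 annotated genes per direction, without the separation criterion for the interaction. Other genes and further members of lists, said to be so, were chosen after their values were seen.

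The alternatives were DESeq2 1.42.0 with its own size factors, edgeR with RLE size factors, edgeR with library totals only, no filter, a filter of at least 10 CPM in 3 libraries, only the 6 libraries compared, the replicate number as a block, limma-trend on log2(TPM + 1) for genes with a mean TPM of at least 1, and leaving out each library in turn. On simulated data with 200 changed genes, the edgeR model recovered 72.3% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 92.4% of those changed 4-fold in attack phase, and 2.87% of its calls there were false. In the interaction it recovered 44.8%, 83.6% and 96.9%, so that small differences between the phases are often missed. Its false calls were 3.52% in intraperiplasmic growth, 3.87% in the interaction and 5.29% in the phase comparison. In the same test 16.9%, 8.06%, 14.9% and 3.85% of the limma-trend calls were false in attack phase, intraperiplasmic growth, the interaction and the phase comparison. In these simulations each gene's base mean was its mean over all 12 libraries, without the real differences between the phases. The rates therefore do not describe genes that have few counts in 1 phase. The real comparisons also called many more genes than the 200 changed here. TPM results served only as an alternative.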

Results

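Gene expression was measured by RNA sequencing in 12 libraries of Bdellovibrio bacteriovorus 109J, with 3 libraries in each of 4 groups. The groups were untreated attack phase, attack phase with DSF, untreated intraperiplasmic growth and intraperiplasmic growth with DSF. The total counts per library were 14292673 to 20057556 in untreated attack phase, 13746980 to 18960226 with DSF in attack phase, 17265258 to 17913366 in untreated intraperiplasmic growth and 13924228 to 19227681 with DSF in intraperiplasmic growth. The most abundant gene with DSF in attack phase was EP01_RS03190, a hypothetical protein gene chosen after its values were seen. It held 12.2% ± 0.193 of the counts there (SD, n = 3), against 4.06% ± 0.150 for the most abundant gene of the untreated attack phase libraries, EP01_RS09610. The 10 most abundant genes held 33.1% ± 0.309 of the counts with DSF and 18.1% ± 0.661 without in attack phase, against 12.9% ± 0.155 and 13.1% ± 0.0614 in intraperiplasmic growth. The TMM factors were 0.536 ± 0.0391 in untreated attack phase, 0.338 ± 0.0265 with DSF in attack phase, 2.38 ± 0.0388 in untreated intraperiplasmic growth and 2.34 ± 0.0808 with DSF in intraperiplasmic growth.

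The first comparison asked what DSF, which the series names as toxic to this predator, changed in free-swimming attack phase cells within 30 min. The genes of a pair of clusters and the gene of a Dps-type protein rose most. The first cluster lies at 120753 to 126805 and encodes an AcrB-type inner membrane pump, a TolC-type outer membrane channel and regulators of the MarR and TetR families, which in other bacteria control drug efflux genes. The pump gene EP01_RS00590 rose from 243 ± 37.5 to 60179 ± 3653 CPM (SD, n = 3), a log2 fold change of 7.95 (SE 0.19, edgeR adjusted p = 4.37e-20). The MarR family gene EP01_RS00585 rose by 8.83 on the log2 scale, from 54.9 ± 1.67 to 24920 ± 2574 CPM. The TetR family gene EP01_RS00600 rose by 7.53, from 212 ± 11.5 CPM, and its annotated span overlaps a gene on the opposite strand. The TolC gene EP01_RS00595 between them rose by 7.39.

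The second cluster, at 1739246 to 1741791, holds a pair of PAP2 family phosphatase genes, a class of membrane enzymes that includes lipid phosphatases, and a pair of genes of unknown function. EP01_RS08250 rose from 0.504 ± 0.276 to 245 ± 18.7 CPM (log2 fold change 8.89, SE 0.20, adjusted p = 2.09e-20), and EP01_RS08245 from 0.885 ± 0.409 to 306 ± 8.06 CPM (8.38). The neighbouring EP01_RS08255 (hypothetical) rose by 8.70 and EP01_RS08260 (DUF3943) by 8.24. These folds start from few reads, with 3 to 8 reads of EP01_RS08250 in each untreated attack phase library, so the SE printed is too small. EP01_RS09060, at 1929453 to 1929959, encodes a Dps-type DNA starvation protection protein, a class that binds DNA and stores iron. It rose from 264 ± 10.1 to 53501 ± 5239 CPM (7.66, SE 0.17, adjusted p = 2.09e-20). EP01_RS03190 rose by 6.91.

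**Figure D1:**
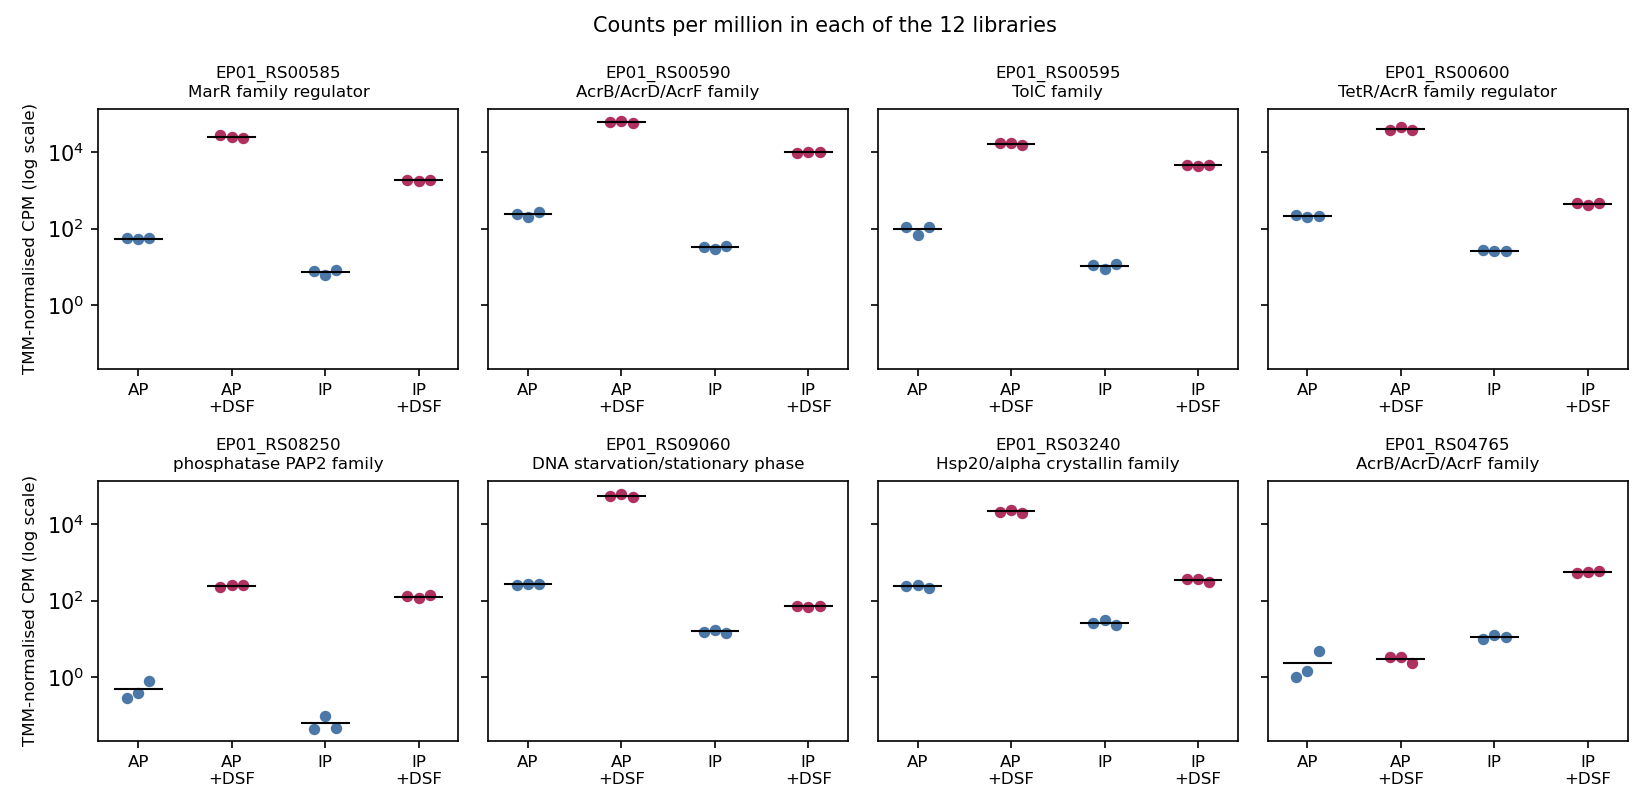
TMM-normalised CPM (log axis) of 8 genes in each of the 12 libraries. Points are libraries, bars are means of 3, blue is untreated and red is with DSF in attack phase (AP) or intraperiplasmic growth (IP). The AcrB gene EP01_RS00590 stood at 243 CPM in untreated attack phase and 60179 with DSF, while EP01_RS04765 stood at 11.3 CPM in untreated intraperiplasmic growth and 560 with DSF.

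The largest falls in attack phase were in genes of different kinds. The adjacent genes EP01_RS09100, a (2Fe-2S)-binding protein at 1937265 to 1938365, and EP01_RS09095, a serine protease at 1936307 to 1937203, had log2 fold changes of -4.31 (SE 0.20, adjusted p = 1.43e-14) and -3.47 (SE 0.12, adjusted p = 9.92e-17). Their levels went from 40.6 ± 1.60 to 2.03 ± 0.908 CPM and from 401 ± 16.2 to 36.0 ± 3.80 CPM (SD, n = 3). The hydrogenase cytochrome b gene EP01_RS16660 fell by 3.03 and the carboxyl-terminal processing protease gene EP01_RS15875 fell by 2.94. The PilZ domain gene EP01_RS04210 and the chemotaxis gene EP01_RS01515 each fell by 2.88. PilZ domains bind the second messenger cyclic di-GMP. EP01_RS07620 (hypothetical) fell by 3.96 and EP01_RS11475 (DUF2203) fell by 3.34. All named genes were higher, or lower, in all 3 DSF libraries than in all 3 untreated ones, which the naming rule required of genes ranked by fold.

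Of 3515 tested genes, 1019 were higher and 1037 lower with DSF in attack phase, 517 and 507 of them at least 2-fold, and 28 were at least 16-fold higher against 2 lower. The DSF and untreated libraries did not overlap for 59.9% of genes, where chance gives 10%. With library totals in place of TMM factors the median gene shifted by -0.67 on the log2 scale and the counts became 394 higher and 1819 lower, so that directions of moderate changes depend on the scaling.

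Chaperone and heat shock genes rose as a list, with 13 of 20 members higher and 3 lower, both over all genes and adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.917 with an estimated correlation). The small heat shock gene EP01_RS03240 (Hsp20), whose product holds unfolding proteins, rose from 240 ± 21.0 to 20989 ± 1971 CPM (log2 fold change 6.45, SE 0.17). The DnaK gene EP01_RS16125 rose by 3.56. Of further members, chosen after their values were seen, the disaggregase gene EP01_RS00550 (ClpB) rose by 2.70 and the GroES gene EP01_RS12305 by 1.34, while EP01_RS09605, another Hsp20 gene, fell by 2.33 and EP01_RS01380, a copper chaperone, fell by 1.71. With library totals 8 chaperone genes were higher and 5 lower, with the list's call kept (adjusted p = 0.030), and with TPM 4 were higher and 11 lower.

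Chemotaxis genes fell as a list, with 20 of 29 members lower and 4 higher, the same adjusted over the list alone (adjusted p = 0.018, and adjusted p = 0.917 with an estimated correlation). EP01_RS16410 fell by 2.00, from 75.5 ± 2.00 to 18.8 ± 1.90 CPM (SD, n = 3). Of further members, chosen after their values were seen, the kinase gene EP01_RS02470 (CheA) fell by 1.08 and the adaptor gene EP01_RS02475 (CheW) fell by 1.57, while EP01_RS09070, annotated as a chemotaxis protein, rose by 3.38. A pair of other members named MotB, EP01_RS01500 and EP01_RS12510, are flagellar motor proteins by their name. With library totals, which moved the median gene by -0.67, 23 members were lower and 2 higher, and the list's call relative to other genes remained (adjusted p = 0.032).

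Transcriptional regulator and sigma factor genes were called higher as a list (adjusted p = 0.018, and adjusted p = 0.917 with an estimated correlation), with 44 of 115 measured members higher and 29 lower, the same adjusted over the list alone. The MarR gene EP01_RS00585 and the TetR genes EP01_RS00600 and EP01_RS06955 were among them, and EP01_RS06955 rose by 4.68, from 2144 ± 147 to 55071 ± 6504 CPM (SD, n = 3). With library totals, which moved the median gene by -0.67, 23 members were higher and 50 lower, while the list's call relative to other genes remained (adjusted p = 0.033).

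Of the other 28 lists none passed the test in attack phase. Translation factors and aminoacyl-tRNA synthetases came closest (9 of 39 higher, 18 lower, camera adjusted p = 0.065, and adjusted p = 0.917 with an estimated correlation). This list was called, at the preset correlation, with library totals and when any 1 of the attack phase libraries was left out. Oxidative stress defence had 14 of 36 genes higher and 7 lower (adjusted p = 0.112), the respiratory chain 10 of 23 higher and 2 lower (0.145), two-component systems 14 of 71 higher and 36 lower (0.208), the TCA cycle 7 of 13 higher and 1 lower (0.399), the flagellum 15 of 49 higher and 23 lower (0.433), and fatty acid beta-oxidation 9 of 16 higher and 5 lower (0.438). The efflux list as a whole had 21 of 66 higher and 15 lower (0.546), and ribosomal proteins 15 of 56 higher and 3 lower (0.691).

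The second comparison asked what the same exposure changed in predators growing inside prey. Genes of the PAP2 cluster and the pump, channel and MarR genes of the pump cluster again rose most. EP01_RS08250 went from 0.0637 ± 0.0286 to 127 ± 11.98 CPM (SD, n = 3; log2 fold change 10.85, SE 0.21, adjusted p = 1.35e-21). EP01_RS08245 rose by 10.43, EP01_RS08260 by 9.73 and EP01_RS08255 by 9.64. These folds again start from few untreated reads, so their size is uncertain and the SE printed is too small. The TolC gene EP01_RS00595, at 124544 to 126073, went from 10.8 ± 1.47 to 4396 ± 50.3 CPM (8.67, SE 0.22, adjusted p = 1.72e-19). The AcrB gene EP01_RS00590 rose by 8.23, from 32.4 ± 3.27 to 9754 ± 159 CPM, and the MarR gene EP01_RS00585 by 7.91, while the TetR gene EP01_RS00600 rose by 4.04. Another AcrB-type pump gene, EP01_RS04765 at 1032815 to 1035934, rose by 5.63 (SE 0.20, adjusted p = 1.13e-15), from 11.3 ± 1.22 to 560 ± 29.3 CPM. In attack phase its log2 fold change was 0.30 (edgeR adjusted p = 0.560). Its levels there were low, at 1.00, 1.45 and 4.91 CPM in untreated libraries 1, 2 and 3 and 3.38, 3.41 and 2.41 with DSF. Untreated library 3 thus lay apart, and the small change there is uncertain.

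Falls in intraperiplasmic growth were smaller. EP01_RS05880, annotated as an auxin-regulated protein, fell by 3.68 (SE 0.14, adjusted p = 2.84e-16), from 95.1 ± 9.62 to 7.41 ± 0.595 CPM (SD, n = 3), and the hypothetical protein gene EP01_RS05870 close by fell by 3.81. The outer membrane beta-barrel gene EP01_RS07965 at 1673445 to 1674152 fell by 3.64 (SE 0.12, adjusted p = 3.64e-17), from 128 ± 13.0 to 10.2 ± 0.812 CPM, and its neighbour EP01_RS07970 (hypothetical) fell by 3.63. The glucosamine 6-phosphate synthetase gene EP01_RS04510, of amino sugar synthesis for the cell wall, fell by 1.93 and the RNA pseudouridine synthase gene EP01_RS04985 fell by 1.88. The subtilisin-like protease gene EP01_RS07740 and the ExbD transporter gene EP01_RS07990 each fell by 1.70.

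In total 827 genes were higher and 1034 lower with DSF in intraperiplasmic growth, 145 and 232 of them at least 2-fold, with 11 at least 16-fold higher and 1 lower. The libraries did not overlap for 62.3% of genes, where chance gives 10%. With library totals the median gene shifted by -0.03 and the counts were 746 higher and 1041 lower. With limma-trend on TPM they were 1291 higher and 540 lower, with a median shift of 0.23.

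Ribosomal protein genes fell as a list, with 36 of 56 lower and 1 higher, the same adjusted over the list alone (adjusted p = 1.6e-04, and adjusted p = 0.919 with an estimated correlation). The falls were moderate, with a list median log2 fold change of -0.42. The S14 gene EP01_RS00140 fell by 1.16 (SE 0.11), from 1335 ± 44.0 to 596 ± 2.67 CPM (SD, n = 3), and the S8 gene EP01_RS00135 fell by 1.10 (SE 0.10), from 1795 ± 16.2 to 840 ± 20.2 CPM. With library totals 33 members were lower and with TPM 17.

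Efflux and drug transport genes rose as a list, with 33 of 66 higher and 16 lower, or 33 and 19 adjusted over the list alone (adjusted p = 1.6e-04, and adjusted p = 0.756 with an estimated correlation). The call also held without the 23 members that matched inside a word (adjusted p = 3.02e-06). Of further members, chosen after their values were seen, EP01_RS13670, a Bcr/CflA family drug transporter gene, rose by 2.12, EP01_RS14820, a TolC family gene, by 1.63, and EP01_RS17490, a macrolide-specific efflux gene, by 0.77. EP01_RS14310, an AcrB family gene, fell by 0.89.

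The list of ATP-dependent proteases rose, with 7 of 10 members higher and 1 lower, the same adjusted over the list alone (adjusted p = 1.65e-04, and adjusted p = 0.279 with an estimated correlation). Its largest rises were in genes whose products are not themselves peptidases: EP01_RS00550 (ClpB), a disaggregase, by 3.18 (SE 0.14), from 72.4 ± 3.96 to 657 ± 69.5 CPM (SD, n = 3), and EP01_RS16095 (ClpS), an adaptor that passes substrates to ClpAP, by 2.88 (SE 0.15). Of further members, chosen after their values were seen, EP01_RS16090 (ClpA) rose by 2.47 and the Lon-type gene EP01_RS07235 by 0.76, while EP01_RS11650 (Lon protease 2) fell by 1.21. Among the lists that did not pass, chaperones had 7 of 20 higher and 3 lower (adjusted p = 0.051), the TCA cycle 9 of 13 higher and 0 lower (0.054), amino acid biosynthesis 13 of 19 higher and 3 lower (0.054), ABC transporters 21 of 119 higher and 55 lower (0.142), and chemotaxis 3 of 29 higher and 6 lower (0.789).

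**Figure D2:**
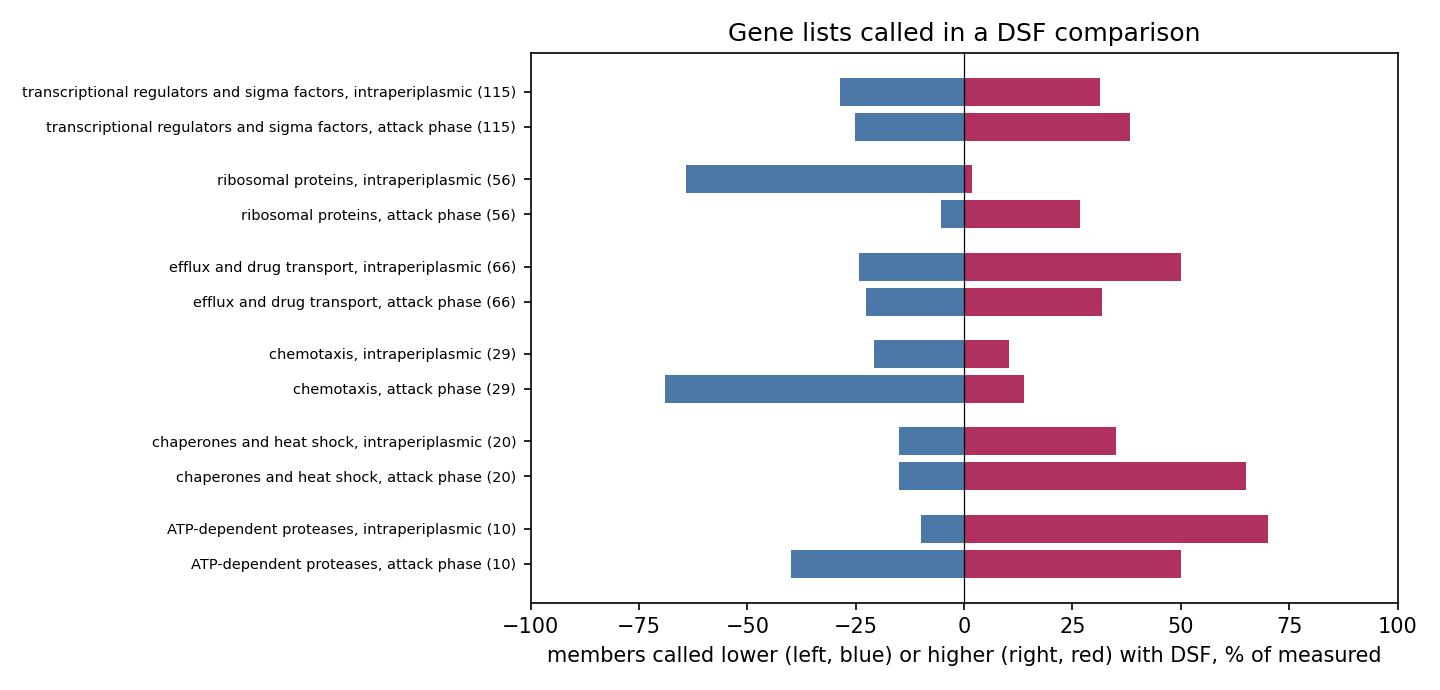
Members of 6 gene lists called higher (red) or lower (blue) with DSF, in percent of measured members, in attack phase and in intraperiplasmic growth, with the number measured in brackets. Ribosomal proteins had 36 of 56 members lower in intraperiplasmic growth and 3 in attack phase, and chemotaxis had 20 of 29 lower in attack phase and 6 in intraperiplasmic growth. In the interaction, chemotaxis, chaperones, regulators and efflux were not called (camera adjusted p = 0.080, 0.102, 0.102 and 0.178).

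Genes higher in both phases numbered 388, where independent lists would share 239.8 (odds ratio 2.88, Fisher's exact p = 1.64e-36, two-sided). Fisher's exact test takes genes as independent, while some adjacent genes moved together, so its p-values here are likely too small. Genes lower in both numbered 347 against 305 (odds ratio 1.31, Fisher's exact p = 0.00075), an excess that was lost with limma-trend on TPM (391 genes, Fisher's exact p = 0.874). A further 211 rose in attack phase and fell in intraperiplasmic growth, and 155 did the opposite, where 299.8 and 244 would be shared by independent lists. At least 2-fold in both phases were 76 genes higher and 47 lower. Across genes, which are not independent replicates, the log2 fold changes of the phases had a Pearson correlation of 0.405 and a Spearman correlation of 0.25.

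**Figure D3:**
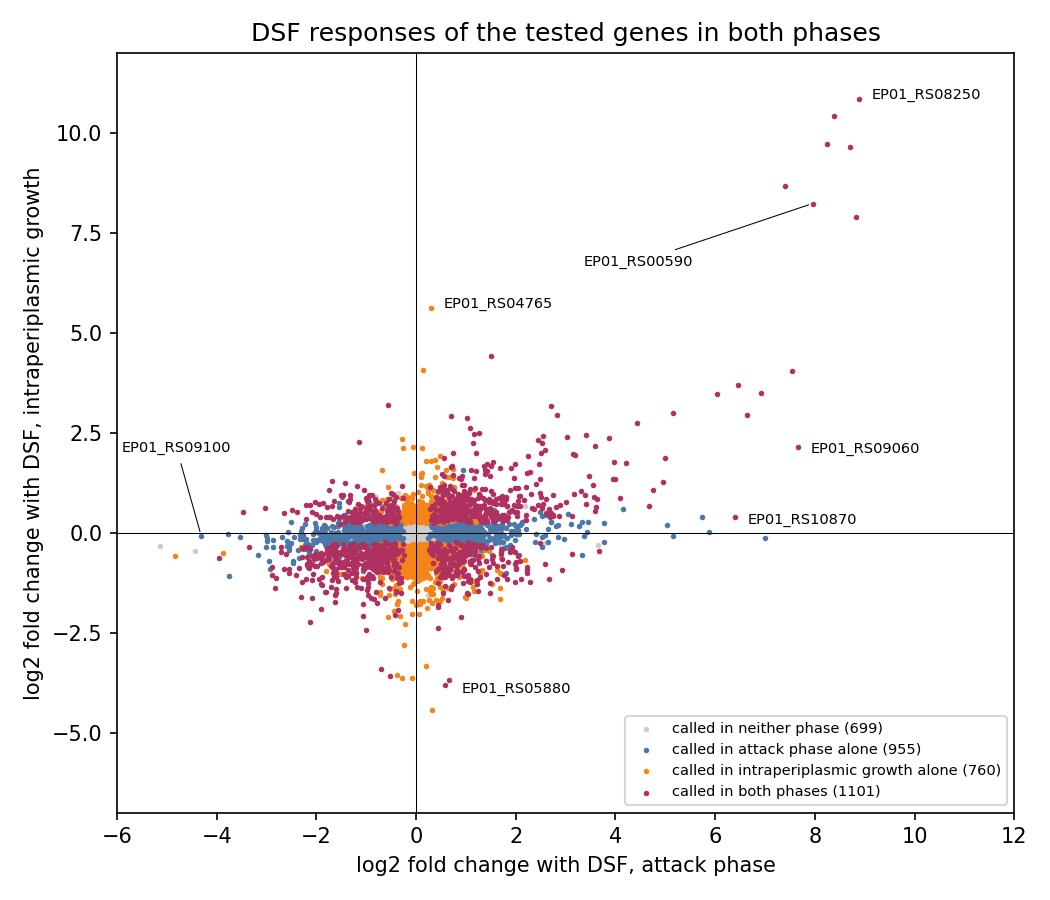
Log2 fold change with DSF in attack phase (x axis) and in intraperiplasmic growth (y axis) of the 3515 tested genes, coloured by the phases in which they passed the test. EP01_RS08250 lies at 8.89 and 10.85, EP01_RS04765 at 0.30 and 5.63, and EP01_RS10870 at 6.40 and 0.38.

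The third comparison tested whether the DSF effect itself differed between the phases. It is given as the log2 fold change in intraperiplasmic growth minus that in attack phase. The flavodoxin family gene EP01_RS10870, whose class carries electrons, had the most negative difference of the named genes, at -6.01 (SE 0.23, adjusted p = 3.80e-15). It rose by 6.40 in attack phase, from 19.8 ± 3.52 to 1672 ± 191 CPM (SD, n = 3), and by 0.38 in intraperiplasmic growth. The Dps-type gene EP01_RS09060 followed at -5.51, having risen by 2.15 in intraperiplasmic growth. The adjacent genes EP01_RS06960 (nitronate monooxygenase) and EP01_RS06955 (TetR family) differed by -4.85 and -4.02, and EP01_RS06960 overlaps a gene on the opposite strand. EP01_RS05880 differed by -4.35, its log2 fold change being 0.66 in attack phase.

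Differences in the other direction were led by the pump gene EP01_RS04765 at 5.33 (SE 0.47, adjusted p = 5.46e-09). Its attack phase levels were low, at 1.00 to 4.91 CPM untreated and 2.41 to 3.41 with DSF. The serine protease gene EP01_RS09095 differed by 3.99, and its log2 fold change was 0.52 in intraperiplasmic growth. The pseudoazurin gene EP01_RS08820, a copper protein of electron transfer, differed by 3.93 (SE 0.26). It rose by 4.07 in intraperiplasmic growth, from 8.13 ± 0.844 to 137 ± 18.5 CPM (SD, n = 3), against 0.14 in attack phase (adjusted p = 0.612). The methyltransferase gene EP01_RS14960 differed by 3.75 and the hydrogenase cytochrome b gene EP01_RS16660 by 3.65, although the deposited TPM of EP01_RS16660 does not follow its counts in every library. The AcrB gene EP01_RS00590 was not called different between the phases, at 0.28 (SE 0.20, adjusted p = 0.249), although it was with library totals (0.93, adjusted p = 5.68e-04), with TPM, and without untreated attack phase library 2 (0.63, adjusted p = 0.013).

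The interaction was positive for 806 genes and negative for 967, 466 and 603 of them at least 2-fold, with 2 at least 16-fold positive and 13 negative. With library totals the median shifted by 0.64 and the counts became 1546 positive and 406 negative. The ribosomal protein list was called negative (34 of 56 negative and 1 positive, adjusted p = 0.0051), as was the respiratory chain (12 of 23 and 2, adjusted p = 0.046). ATP-dependent proteases (6 of 10 positive and 1 negative, adjusted p = 0.029) and translation factors with aminoacyl-tRNA synthetases (17 of 39 and 5, adjusted p = 0.029) were called positive. Counts adjusted over each list alone were the same, and each of these lists had adjusted p = 0.852 with an estimated correlation. With library totals the ribosomal list had 8 members positive and 6 negative (adjusted p = 0.093) and the respiratory chain 5 and 6 (adjusted p = 0.108), so neither was called. The respiratory chain call was also lost with the replicate number as a block (camera adjusted p = 0.085). It was lost as well without untreated attack phase library 1 (0.114) and without DSF attack phase library 2 (0.051) or 3 (0.12). The call of ATP-dependent proteases was lost without DSF attack phase library 3 (0.061). With TPM, which moved the median gene by 1.30, the ribosomal list had 40 positive and 0 negative, with a list median of 0.74 against 0.97 over all genes. The respiratory chain genes EP01_RS13160 and EP01_RS13155, cytochrome c oxidase subunits chosen after their values were seen, rose by 0.63 and 0.69 in attack phase and had log2 fold changes of -1.06 and -0.69 in intraperiplasmic growth.

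The last comparison set untreated intraperiplasmic growth against untreated attack phase, the background of the DSF effects. Genes with roles in motility and signalling were among those that fell most. The PilZ domain gene EP01_RS06910 fell by 11.74 (SE 0.24, adjusted p = 1.15e-22), from 4033 ± 621 to 1.18 ± 0.262 CPM (SD, n = 3). The flagellar hook-associated gene EP01_RS17050 had a log2 fold change of -10.99, the flagellar export chaperone gene EP01_RS17055 (FliS) -10.95, the lytic transglycosylase gene EP01_RS08360 -10.92 and the flagellin gene EP01_RS13725 -10.83. EP01_RS12010, annotated as a DNA inversion stimulation factor, rose by 8.03 (SE 0.19, adjusted p = 1.01e-21), from 0.764 ± 0.483 to 212 ± 8.92 CPM. The nuclease gene EP01_RS14525 rose by 7.51, the ATP synthase subunit C gene EP01_RS11880 by 7.51, the iron-regulated protein A gene EP01_RS16895 by 7.40 and the maltose transport permease-like gene EP01_RS15820 by 7.38.

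In all, 1800 genes were higher and 1505 lower in intraperiplasmic growth, 1634 and 1349 at least 2-fold, and the libraries of the phases did not overlap for 94.4% of genes, where chance gives 10%. With library totals the median shifted by 2.15, to 2366 higher and 984 lower, and with RLE size factors by -0.39. Of 31 lists 17 were called with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.184. All 56 ribosomal protein genes and all 9 ATP synthase genes were higher (adjusted p = 7.94e-18 and 2.95e-05), as were 34 of 39 translation genes (6.21e-07), 21 of 23 respiratory chain genes (6.28e-06), 24 of 25 nucleotide biosynthesis genes (3.44e-05), 20 of 24 DNA replication genes (0.00055), 20 of 23 fatty acid and phospholipid synthesis genes (0.00070), 12 of 13 TCA cycle genes (0.0012), 82 of 119 ABC transporter genes (0.024), 26 of 36 nucleases (0.042), 19 of 28 DNA repair genes (0.044) and 9 of 10 iron genes (0.044). Lower were 47 of 49 flagellum genes (1.38e-14), 20 of 22 cyclic di-GMP signalling genes (1.29e-06), 15 of 18 pilus genes (7.73e-05), 26 of 29 chemotaxis genes (1.07e-04) and all 10 ATP-dependent protease genes (0.00093). The DNA repair call was lost without the 9 members that matched inside a word (adjusted p = 0.221), and when any library but untreated attack phase library 2 was left out (0.051 to 0.127). These counts of members were the same adjusted over each list alone. With library totals 8 ATP-dependent protease genes were lower and 1 was higher.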

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

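The tests of scaling between libraries were chosen only after the results they concern were seen, while the tests of gene length, counts per gene, abundant genes, depth and splits were set before. The results in this part were picked out because the DSF effect differed between the phases by the test of the interaction, 806 genes being positive and 967 negative (intraperiplasmic minus attack phase). In 2 of 100 splits drawn within the phases, the real one included, as many genes were called as the real 1773. At the 0.05 level this speaks only against no DSF effect in either phase. It does not test against equal effects, since splits that mix the treatments carry the DSF effect into the spread within groups. The highest other split gave 2057 genes. It is the split that swaps DSF and untreated labels in intraperiplasmic growth, so that it adds the DSF effects of the phases instead of subtracting them and points to the shared response. For the single comparisons the 10 splits of 6 libraries are too few for a share under 0.05, and 1 of the 10 gave as many genes each time, the real one. The real counts were 2056 in attack phase, 1861 in intraperiplasmic growth and 3305 between the phases, and the highest other split gave 0 each time. The other splits mix the groups compared, which widens the spread within groups, so low counts there were built in.

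Of the 38 genes named in the DSF comparisons and the interaction, 37 differed between the phases in the main fit, and EP01_RS00590 was called under 4 alternatives only. The response was more positive in intraperiplasmic growth for the PAP2 cluster, by 1.97 for EP01_RS08250, 2.05 for EP01_RS08245, 0.94 for EP01_RS08255 and 1.49 for EP01_RS08260, and for the efflux genes EP01_RS00595 by 1.27 and EP01_RS04765 by 5.33. The PAP2 differences rest on few untreated reads in both phases. EP01_RS08250 lay at 0.30 to 0.82 CPM in untreated attack phase and at 0.046 to 0.097 in untreated intraperiplasmic growth. With DSF its TMM-normalised level was higher in attack phase (223 to 257 CPM) than in intraperiplasmic growth (114 to 137 CPM). That order comes from the TMM factors of the DSF libraries, 0.338 ± 0.0265 in attack phase and 2.34 ± 0.0808 in intraperiplasmic growth. With library totals alone the order is reversed. The response was also more positive for genes that fell in attack phase, by 4.24 for EP01_RS09100, 3.99 for EP01_RS09095, 3.65 for EP01_RS16660, 2.23 for EP01_RS15875, 2.69 for EP01_RS04210, 2.51 for EP01_RS01515, 3.34 for EP01_RS07620, 2.98 for EP01_RS11475 and 2.48 for EP01_RS16410. Some of these already had low TMM-normalised CPM in untreated intraperiplasmic growth. The TMM factors there were 2.38 ± 0.0388, so such levels are not a floor of a few reads. A large fall could still have been seen. EP01_RS09100 lay at 1.16 to 1.27 CPM, EP01_RS15875 at 0.67 to 1.10 and EP01_RS01515 at 0.61 to 1.20, while EP01_RS16660 lay at 92.9 to 95.7. Further positive differences were 0.48 for EP01_RS00550, 1.87 for EP01_RS16095, 3.93 for EP01_RS08820 and 3.75 for EP01_RS14960.

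The response was more negative in intraperiplasmic growth for the regulator genes EP01_RS00585 (-0.92), EP01_RS00600 (-3.50) and EP01_RS06955 (-4.02), for the stress genes EP01_RS09060 (-5.51), EP01_RS03240 (-2.76) and EP01_RS16125 (-2.68), and for EP01_RS10870 (-6.01) and EP01_RS06960 (-4.85). It was also more negative for genes that fell in intraperiplasmic growth, EP01_RS05880 (-4.35), EP01_RS07965 (-3.56), EP01_RS04510 (-1.57), EP01_RS04985 (-2.11), EP01_RS07740 (-2.17), EP01_RS07990 (-1.33), EP01_RS05870 (-4.40), EP01_RS07970 (-3.35), EP01_RS00135 (-0.92) and EP01_RS00140 (-1.24). Some of these were low in untreated attack phase, such as EP01_RS04985 (0.80 to 1.13 CPM) and EP01_RS07990 (1.97 to 3.30), while EP01_RS04510 lay at 49.8 to 59.2 CPM there. Small differences depended on the processing. With library totals the differences of EP01_RS00585 (-0.28, adjusted p = 0.222), EP01_RS00135 (-0.27, 0.176) and EP01_RS07990 (-0.70, 0.055) were no longer called. With TPM those of EP01_RS00585 (0.73), EP01_RS00135 (0.48) and EP01_RS00140 (0.23) changed sign. Of 20 alternatives, EP01_RS08255 (adjusted p = 0.047 in the main fit) lost its call in 8, EP01_RS00550 in 4, and EP01_RS08250 and EP01_RS08260 in 1 each. The lists that differed were ribosomal proteins (adjusted p = 0.0051), ATP-dependent proteases (0.029), translation factors and aminoacyl-tRNA synthetases (0.029) and the respiratory chain (0.046). None was called with an estimated correlation (adjusted p = 0.852 for each), and with library totals the calls of ribosomal proteins (0.093) and the respiratory chain (0.108) were lost.

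The first pattern weighed was the fall of ribosomal protein genes in intraperiplasmic growth and its difference from attack phase. Gene length is argued against as the whole cause, since the list median of -0.42 lay at percentile 0 of 10000 random lists matched on coding length, the lowest of which was -0.39, and lower counts in attack phase are argued against as well, since 29 of the 36 calls in intraperiplasmic growth remained after thinning to the attack phase level. Scaling stays open for the fall itself, where library totals moved the median gene by only -0.026 and so test nothing. RLE size factors kept 33 members lower (list median -0.38, all genes -0.03), but they too moved the median gene by only 0.039. The 17 members lower with TPM do not decide it, as that fit changes the unit, the filter and the test along with the scaling. Scaling also stays open for the sign of the difference between the phases. Only 6 of the 34 negative calls were also called with library totals, but these moved all genes at once, so that count decides nothing. The list median lay below that of all genes by nearly as much (-0.53 against -0.55). A shift shared by all genes leaves this gap nearly as it was, so it decides nothing either. The camera call of the list did depend on the choice, with adjusted p = 0.0051 under TMM factors and 0.093 with library totals. The growth phase itself, which the design names, stays open as an untested explanation.

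The second pattern was that DSF changed more genes at least 2-fold in attack phase than in intraperiplasmic growth, 1024 against 377, a ratio of 2.72. Without the 10 most abundant genes of every library, 32 genes in all, the ratio was 2.80. TMM already trims extreme genes when it sets its factors, so this could hardly have moved the ratio and decides little about abundant genes. Depth per gene is argued against, since the ratio was 3.93 among 869 genes with a mean count of at least 200 in both phases. Scaling of the attack phase libraries is argued against, since the ratio was 2.70 at the shared factor that gave the fewest genes there, while scaling of the intraperiplasmic libraries stays open, since library totals (ratio 3.54) hardly moved them and a log2 factor of 0.4 shared by their genes would bring the ratio under 1.5. A stronger response of attack phase cells may be considered as a hypothesis, found and tested on the same data, and the dose each cell met was not measured.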

How the results depend on the processing

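The TPM fit without genes of mismatched TPM, the lists without matches inside words and the interaction of genes named in a DSF comparison were chosen after seeing the data. For named genes in the comparison that named them, 1226 values under the alternatives kept their direction and their side of the threshold, and the 1 exception was the interaction of EP01_RS16660 with TPM (adjusted p = 0.0502), whose deposited TPM does not follow its counts. Of the interactions of the 38 genes named in the DSF comparisons or the interaction, 731 values stayed, 18 lost their call, 4 gained one, all of EP01_RS00590, and 6 changed sign. The last were 0.73 for EP01_RS00585, 0.48 for EP01_RS00135 and 0.23 for EP01_RS00140, each with TPM and the same without the mismatched genes, and this fit changes the unit, the filter and the test along with the scaling. DESeq2, RLE size factors, no filter, the 10 CPM filter and the 6-library fits kept every count of genes they give within 1.5 times its value, and the 6-library fits give none for the interaction. Library totals changed counts by moving all genes at once, with a median shift of -0.67 in attack phase, -0.03 in intraperiplasmic growth, 0.64 in the interaction and 2.15 between the phases. They gave 394 higher and 1819 lower genes in attack phase (202 and 1179 at least 2-fold), 1546 and 406 in the interaction (1064 and 240), 984 lower between the phases (870), and 188 genes higher and 598 lower in both phases. TPM gave 152 higher and 2312 lower in attack phase (83 and 1226), 1291 and 540 in intraperiplasmic growth (69 at least 2-fold lower), 2402 and 231 in the interaction (1519 and 75), 864 at least 2-fold lower between the phases, and 114 higher in both phases and 391 lower (Fisher's exact p = 0.874), with median shifts of -1.08, 0.23, 1.30 and 1.38. Without the mismatched genes these were 154 and 2306 (83 and 1216), 1294 and 542 (69), 2402 and 234 (1516 and 75), 862, and 116 and 394 in both phases (Fisher's exact p = 0.709 for the latter). Which scaling is right for total RNA per cell cannot be read from these libraries.

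The estimated correlation called 0 lists in each comparison, while fry, which asks whether the genes of a list move one way, called 20, 20, 17 and 28 lists. Library totals called 2 lists in the interaction, and in attack phase they added translation factors and aminoacyl-tRNA synthetases, as did leaving out any 1 attack phase library. In intraperiplasmic growth library totals added chaperones (4 lists). The lists without matches inside words added regulators and sigma factors to the interaction (5 lists). Leaving out 1 library gave 723 to 1015 genes higher in attack phase, lowest without untreated attack phase library 2. It gave 3 to 5 lists in attack phase, with 5 without untreated attack phase library 3, and 3 to 6 lists in intraperiplasmic growth. There 5 or 6 were called without untreated attack phase library 2 or 3, DSF attack phase library 1, 2 or 3, untreated intraperiplasmic library 1 or DSF intraperiplasmic library 2, where chaperones, the TCA cycle or amino acid biosynthesis joined. The interaction had 2 to 5 lists, with 2 without DSF attack phase library 3, and the phase comparison 16 to 17. The cause of these list changes was not tested.

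The replicate number as a block gave 1059 higher and 1083 lower genes in attack phase and 947 and 1169 in intraperiplasmic growth, ended the interaction calls of the respiratory chain (adjusted p = 0.085) and of EP01_RS08255 (adjusted p = 0.0557) and added chaperones to the lists called in intraperiplasmic growth. The labels do not say that a number joins libraries, although parts of a culture may have gone to both treatments. Across genes, after group means were removed, libraries of the same number correlated at -0.0043, 0.056 and 0.048 in attack phase. In intraperiplasmic growth they correlated at 0.428, 0.271 and 0.0935, against -0.374 to 0.144 for different numbers, so a shared culture or batch there stays open. Depth limits genes with few reads, as 102 of 3617 were not tested.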

Other observations

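The tests of genes beside regulators and the count of product names were chosen only after the results were seen, and the tests of a shift between phase profiles were set before. In attack phase, 4 genes annotated with the cbb3-type cytochrome oxidase or its assembly rose with DSF. They were chosen after their values were seen, and the list that covers the class, the respiratory chain, did not pass there (adjusted p = 0.145, and 0.917 with an estimated correlation). EP01_RS09015 (CcoS) rose by 3.41 on the log2 scale, EP01_RS18465 (CcoQ/FixQ) by 2.51, EP01_RS09030 (CcoG) by 2.41 and EP01_RS09020 (cbb3 subunits I/II) by 1.76, and they rose by 0.72, 0.88, 1.21 and 0.77 in intraperiplasmic growth. Also chosen after their values were seen were the genes that follow. The TCA cycle gene EP01_RS01165 (aconitase AcnA) rose by 2.02 in attack phase and 0.52 in intraperiplasmic growth. In intraperiplasmic growth the 7 adjacent genes from EP01_RS07955 to EP01_RS07985, hypothetical but for the beta-barrel gene EP01_RS07965, fell together. The log2 fold changes were -3.41 for EP01_RS07955, -3.59 for EP01_RS07960, -3.55 for EP01_RS07975, -3.34 for EP01_RS07980 and -2.81 for EP01_RS07985.

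Among lists not yet described, in attack phase TonB, ExbBD and TolQR genes had 16 of 29 higher and 5 lower (adjusted p = 0.487), ABC transporters 21 of 119 and 37 (0.524), peptidoglycan and cell division 18 of 61 and 20 (0.553), cyclic di-GMP signalling 6 of 22 and 7 (0.558), ATP synthase 5 of 9 and 0 (0.558), peptidases and proteases 29 of 95 and 32 (0.617), DNA repair 7 of 28 and 12 (0.691) and iron uptake and storage 3 of 10 and 2 (0.834). In intraperiplasmic growth, oxidative stress defence had 17 of 36 higher and 6 lower (0.142), regulators 36 of 115 and 33 (0.181), DNA repair 9 of 28 and 4 (0.380), ATP synthase 0 of 9 and 4 (0.392), pilus genes 1 of 18 and 8 (0.427), peptidoglycan and cell division 11 of 61 and 26 (0.599), the respiratory chain 4 of 23 and 9 (0.623) and translation 13 of 39 and 11 (0.835).

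A hypothesis was that DSF moves attack phase cells towards the profile of intraperiplasmic growth. Of genes at least 8-fold higher in untreated intraperiplasmic growth (1085) and at least 8-fold lower (897), the median log2 fold changes with DSF in attack phase were 0.34 and -0.24, a difference of 0.58 against at most 0.04 in 100 simulated unchanged groups. The simulated groups held no DSF effect at all, so they bound only the spread of sampling. They do not test against a DSF response unrelated to the phases. The phase difference and the DSF response also share the untreated attack phase libraries, whose noise pushes the difference towards the hypothesis. The simulated groups were drawn around the observed untreated means, so they cannot show this. Of the 1085 genes 318 rose and 98 fell, and of the 897 genes 282 rose and 419 fell. The difference of 0.58 would go with a partial shift, small beside the phase difference itself, and may equally reflect a general loss of abundant attack phase transcripts. The reverse shift was argued against, since the difference in intraperiplasmic growth was -0.00036, where at least 0.5 was required.

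A second hypothesis was that genes next to TetR or MarR family regulators rise more often than others. It came from the pump cluster, which was therefore left out of the test. In attack phase 12 of 27 genes within 2 positions of the other 7 regulators rose at least 2-fold (44.4%, against 14.6% of all genes), a share reached by a fraction of 0.0014 of circular shifts of the positions, the observed one included. In intraperiplasmic growth 2 of 27 did (7.41% against 4.02%, fraction 0.199), which decides nothing. Values of some of these neighbours had been seen when the test was set, so it does not stand as an independent test.

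The authors' deposited table, in which some corrected p-values exceed 1, holds 105 genes higher and 1471 lower in attack phase at a corrected p under 0.05, and 935 higher and 332 lower in intraperiplasmic growth. Across genes its log2 ratios correlated with the count-based ones at 0.977 and 0.988, with median differences of -1.40 and 0.25. Genes under 300 bp held 60.6% ± 0.963 of the TPM in untreated attack phase (SD, n = 3) but 3.20% ± 0.0249 of the counts. In 48 genes the deposited TPM departed by more than 0.5 on the log2 scale from the gene's usual ratio to its counts in some library with at least 50 counts (99 values), 12 genes had a blank TPM, and 50 genes had either. Of these 50, 38 have a comma or square bracket in their product name, against 7 of the other 3568 rows (Fisher's exact p = 2.05e-72). EP01_RS14235, one of them and chosen after its values were seen, has an authors' ratio of 59.0 in intraperiplasmic growth and a count-based log2 fold change of 0.23.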
